A study of Mus musculus with 4 samples.

How the data were processed

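Microglia, the resident macrophages of the brain, had been isolated from mice at postnatal day 11, and their RNA was sequenced on an Illumina HiSeq instrument, per the labels' protocols. The genotype labels gave 2 libraries from Pd1fl/fl mice, in which the gene for the inhibitory receptor PD-1 is flanked by recombination sites, and 2 libraries labelled Pd1cKO-Cx3, a conditional knockout of that gene. The labels do not spell out the driver behind "Cx3", nor whether the controls carried it. They also do not say whether replicates came from separate animals, so p-values measure only the spread between these samples. The sex-linked genes Xist (13374 and 0 counts) and Ddx3y (0 and 1916) in Pd1fl/fl replicates 1 and 2 argue against a single animal behind both controls. Between the libraries labelled Pd1cKO-Cx3 the spread may be technical.

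The authors deposited 4 tables, each joining 1 library labelled Pd1cKO-Cx3 with 1 control library, and each library stood in 2 tables. The counts in these deposited tables are raw reads per Ensembl gene, per the file headers and their whole-number values. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.0 without saying how each was used or whether counting used strand. The same notes name the mouse build mm9, but 18680 of 20276 gene identifiers (92.1%) had exactly the position that GENCODE M21 gives on GRCm38, so the coordinates printed are those of the deposited tables and are read as GRCm38. The deposited CPM columns are counts scaled to the library total, with a count of 0 replaced by 0.5, as their values show. The deposited ratio and log2 fold change columns compare the CPM of the 2 libraries of a table. The deposited p-value columns come from a test of 2 libraries whose tool is not given in the sources used here. The authors marked a gene as significant exactly where p was under 0.05 and the absolute log2 fold change was over 1, a rule with 0 exceptions in each table.

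A library's counts were identical in both of its tables, with 0 differences in each library. In 74515 pairs of a gene and a table with both counts known, a gene was listed only where both counts were at least 1 or either was at least 5. A gene missing from both tables of a library therefore had at most 4 counts there, and was given 0. This applied to 3158 of the 20308 genes in any table and to 0 of the genes tested. Symbols that a spreadsheet had turned into dates were restored for 22 genes. The total counts were 15908954 and 14854625 in Pd1fl/fl replicates 1 and 2 and 14258420 and 15486984 in the libraries labelled Pd1cKO-Cx3 replicates 2 and 3. The 10 most abundant genes took 8.91% to 9.91% of the counts, and mitochondrial genes took 1.02% to 1.60%, more in both libraries labelled Pd1cKO-Cx3 than in both controls.

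Genotypes were compared with edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter, the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05, on 15097 genes. Fold changes are log2, given as the libraries labelled Pd1cKO-Cx3 minus Pd1fl/fl, and CPM values are relative to the library total, without TMM factors, with SD over 2 libraries. Where every library of a group was at 0 counts, a fold is a lower bound computed against a floor of 3 counts per library. Where a group had 1 to 3 counts, the ratio of summed counts is given with its exact 95% binomial interval. Such floors and intervals cover counting error only.

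Lists of genes for microglial states, phagocytosis, vascular and matrix factors, signalling, metabolism, cell cycle and other cell types were fixed before the data were examined. Lists with at least 5 tested genes were compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 26 lists. Biological process terms from the annotation columns with 15 to 300 tested genes were tested in the same way. Genes were named by a rule also fixed before the data were examined. The rule took the targeted gene and its ligands, up to 12 genes per direction with the largest change past the threshold at a mean of at least 5 CPM with no overlap between groups, the 3 members of each list with the smallest p and up to 2 more in lists that passed, 6 microglial genes, and Xist and Ddx3y. Predicted genes were left out. Any other gene named was chosen after its values were seen. The ligand gene Pdcd1lg2, also in the rule, is not analysed here, and 3 other genes that the rule names are not reported here.

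The same scripts were tested on simulated data. Each of 10 simulations of this comparison over 15097 genes had 200 changed genes, besides a list of 30 other genes shifted 2-fold. Among the 200, edgeR found 10.9% of 2-fold and 47% of 4-fold changes, and 93.2% of 4-fold changes above 20 CPM. Of its 710 calls, 74 (10.4%) were false, with calls of shifted list genes counted as true. DESeq2 1.42.0 found 26.6% and 59.5% of these changes, with 34.1% of 1485 calls false. camera found a list of 30 genes shifted 2-fold in 10 of 10 simulations and called an unshifted list in 1. Simulated genes were drawn independently, so these counts do not cover lists of correlated genes. The estimated correlation was 0.367 in the interferon list and 0.617 in the cell cycle list.

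Alternatives changed 1 choice at a time, except that DESeq2, and camera on its statistics, ran on the 20308 genes with a count above 0, so both the tool and the filter changed there. They used RLE or upper-quartile factors or library size alone, other filters, DESeq2, limma-voom, limma-trend, other thresholds, camera with an estimated correlation or on DESeq2 statistics, fry, and leaving out each library. In the last case the filter was applied again and 1 group holds a lone library, which is assumed to vary like the other group. Missing counts taken as 4, protein-coding genes alone, DESeq2 on the 15097 genes that edgeR tested, and the homeostatic list without Cx3cr1 were added after seeing the data.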

Results

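RNA from microglia isolated at postnatal day 11 was compared between 2 Pd1fl/fl libraries and 2 libraries labelled Pd1cKO-Cx3, in a study of PD-1 in microglia and of the pruning of brain vessels during development. Depth was similar in the 4 libraries, from 14258420 to 15908954 counts, with 16763 to 18431 genes counted. The Pearson correlation of log2 CPM was 0.891 between the 2 controls and 0.930 between the 2 libraries labelled Pd1cKO-Cx3. Across the groups it ranged from 0.884 to 0.920, so the controls did not lie closest to each other.

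The targeted gene was the first to be examined. Pdcd1, which encodes PD-1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553, GRCm38), had 0 and 43 counts in Pd1fl/fl replicates 1 and 2. It had 179 and 154 counts in the libraries labelled Pd1cKO-Cx3 replicates 2 and 3. The means were 1.45 ± 2.05 CPM (SD, n = 2) and 11.2 ± 1.85 CPM (SD, n = 2), so the level went against the labels, and every direction given in this text follows those labels. The log2 fold change of 2.95 ± 1.48 (SE) did not pass edgeR's quasi-likelihood test (adjusted p = 0.695). It was 1.94 without Pd1fl/fl replicate 1 (adjusted p = 0.349). Without Pd1fl/fl replicate 2, the remaining control was at 0 counts and the fitted value of 10.4 is set by the prior count (adjusted p = 0.0645). The tables count whole genes, so reads from parts of the gene outside a deletion cannot be set apart. Cd274, which encodes the PD-1 ligand PD-L1, had 3.85 ± 0.554 CPM in Pd1fl/fl and 7.20 ± 2.51 CPM in the libraries labelled Pd1cKO-Cx3 (SD, n = 2), a difference within the error of the test (edgeR adjusted p = 0.758).

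Microglial identity genes were abundant in all 4 libraries. Csf1r, the receptor on which microglia depend for survival, had 17048 ± 180 CPM in Pd1fl/fl and 16219 ± 943 CPM in the libraries labelled Pd1cKO-Cx3 (SD, n = 2). Tmem119 had 8326 ± 137 and 8179 ± 231 CPM, and Aif1 224 ± 12.5 and 232 ± 23.5 CPM in the same order. None of these 3 genes passed the edgeR test (adjusted p from 0.771 to 0.980). For Tmem119 and Aif1 the sign of the fold change turned in at least 1 fit without a library. Xist, transcribed from the inactive X chromosome, had 13374 counts in Pd1fl/fl replicate 1 and 0 in the others. The Y-linked Ddx3y had 0 counts in Pd1fl/fl replicate 1 and 1916, 1891 and 2064 in the others, so 1 control library differed in sex-linked expression from the remaining 3. Mitochondrial genes took 1.24% and 1.02% of the counts in Pd1fl/fl replicates 1 and 2 and 1.48% and 1.60% in the libraries labelled Pd1cKO-Cx3 replicates 2 and 3. This difference in a measure that can follow RNA quality stands beside each gene group below.

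**Figure D1:**
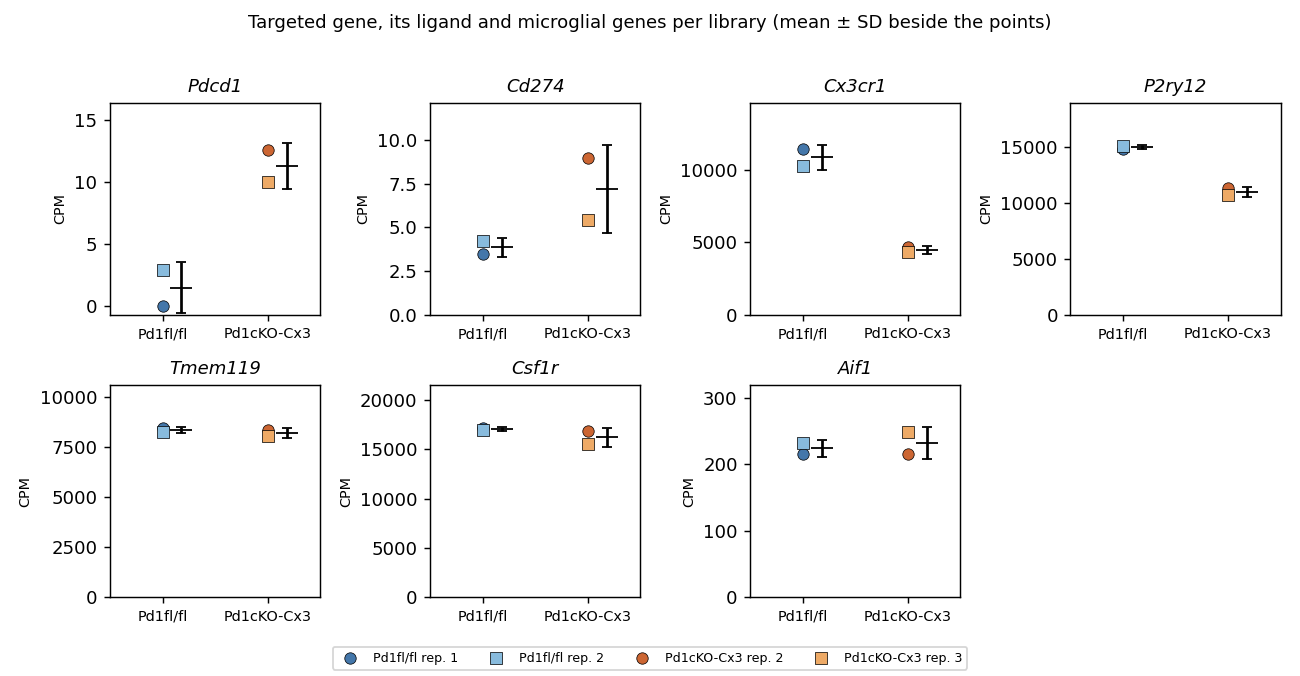
CPM (linear axis) of the targeted gene Pdcd1, its ligand gene Cd274 and 5 microglial genes in each of the 4 libraries, with the mean and SD of the 2 libraries of each group beside the points. Pdcd1 lies higher in the libraries labelled Pd1cKO-Cx3, and Cx3cr1 lies lower, at 4479 against 10869 CPM.

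Between the genotypes, 3 genes were higher and 3 were lower in the libraries labelled Pd1cKO-Cx3. The antiviral enzyme gene Oas2 (chromosome 5, 120730333 to 120749853) rose from 15.02 ± 3.99 to 178 ± 26.7 CPM (SD, n = 2), a log2 fold change of 3.56 ± 0.25 (SE, edgeR adjusted p = 0.0369). Sp100, a nuclear body protein gene induced by interferon (chromosome 1, 85649988 to 85709998), rose from 37.8 ± 2.201 to 155 ± 10.8 CPM, with 2.03 ± 0.16 on the log2 scale (edgeR adjusted p = 0.0466). Cx3cr1, the fractalkine receptor gene of microglia (chromosome 9, 119901616 to 120069879), fell from 10869 ± 856 to 4479 ± 253 CPM, with a log2 fold change of -1.29 ± 0.07 (edgeR adjusted p = 0.0251). Fcrls, a microglial Fc receptor-like gene (chromosome 3, 87250758 to 87263738), fell from 5504 ± 130 to 3039 ± 120 CPM, with -0.87 ± 0.06 (edgeR adjusted p = 0.0369). Tpm3-rs7 (chromosome 14, 113314608 to 113316713) rose from 42.7 ± 3.08 to 902 ± 14.1 CPM, while Tpm3, a tropomyosin gene (chromosome 3, 90072649 to 90100902), fell from 1433 ± 117 to 352 ± 42.5 CPM (edgeR adjusted p = 0.000762 and 0.0251). These last 2 genes are near-identical copies that can share reads, and their single values are uncertain.

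The test covered 15097 genes, of which 1221 had an unadjusted p under 0.05, 750 higher and 471 lower. On the same 15097 genes, a setting added after seeing the data, DESeq2 called 234 genes, 179 higher and 55 lower, among them all 6 of edgeR's, but 34.1% of its calls were false in simulated data. On 20308 genes with any count it called 220, and edgeR called 32 on these. Without Pd1fl/fl replicate 2, edgeR called 21 genes. The call of Oas2 was lost without the library labelled Pd1cKO-Cx3 replicate 2 or 3, at log2 fold changes of 3.40 and 3.71. That of Sp100 was lost without Pd1fl/fl replicate 1 (1.97) and without the library labelled Pd1cKO-Cx3 replicate 2 (2.10) or 3 (1.97). It was also lost with upper-quartile factors (edgeR adjusted p = 0.0583). The call of Fcrls was lost without Pd1fl/fl replicate 1 (-0.84).

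The interferon response genes were higher as a group in the libraries labelled Pd1cKO-Cx3. Of 37 members, 36 lay above both controls in both of these libraries. Chance puts 1 gene in 6 on that side, but the members had an estimated correlation of 0.367. The 36 are thus not independent of each other. The median log2 fold change was 2.13 (camera adjusted p = 2.4e-25, but adjusted p = 0.407 with an estimated correlation). The latter setting rests on 2 residual degrees of freedom, here and for each list below. Over all genes tested 2 members passed edgeR's threshold, and adjusted over the list alone 34 rose and 3 did not pass. Ifit1, Ifit2 and Ifit3, which encode antiviral proteins that bind foreign RNA or their partners, had log2 fold changes of 3.64 ± 0.37, 2.61 ± 0.21 and 2.72 ± 0.24 (SE). Ifit1 stood at 3.49 ± 0.750 CPM in Pd1fl/fl and 43.9 ± 13.3 CPM in the libraries labelled Pd1cKO-Cx3 (SD, n = 2). The direction and the camera call held in each of the 4 fits without a library, with medians from 1.81 to 2.48. Marker lists of other cell types also had positive medians, 0.85 for border-associated macrophages, 0.91 for endothelium, 1.04 for mural cells and fibroblasts and 1.14 for lymphocytes.

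**Figure D2:**
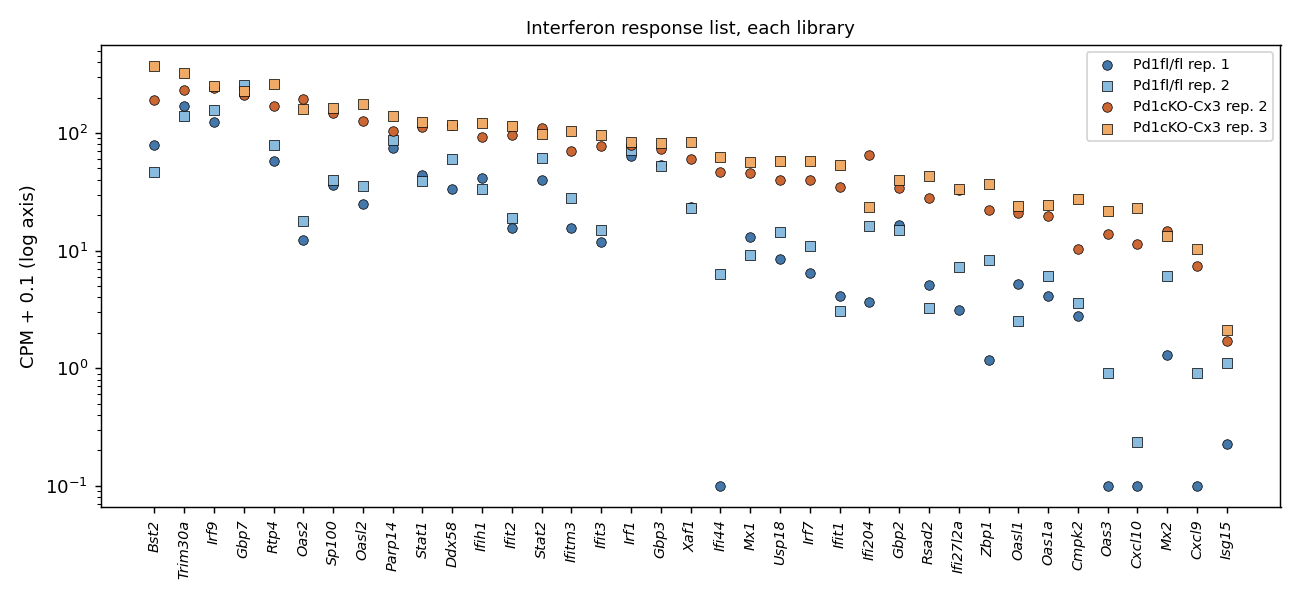
CPM + 0.1 (log axis) of the 37 genes of the interferon response list in each of the 4 libraries, ordered by their mean in the libraries labelled Pd1cKO-Cx3. For 36 genes both libraries labelled Pd1cKO-Cx3 lie above both Pd1fl/fl libraries.

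Genes of antigen presentation were also higher as a group, with a median log2 fold change of 0.61 over 22 members (camera adjusted p = 4.5e-05, adjusted p = 0.407 with an estimated correlation). None passed edgeR over all genes tested, and adjusted over the list alone 5 rose and 17 did not pass. DESeq2 on 20308 genes called the same 5 over all genes. These 5 all belong to the class I pathway, which presents peptides from inside the cell. The class I heavy chain genes H2-D1 and H2-K1 went from 455 ± 8.25 to 1288 ± 280 CPM and from 394 ± 6.55 to 967 ± 172 CPM (SD, n = 2). B2m, the light chain gene, went from 2158 ± 55.4 to 3404 ± 99.7 CPM. H2-T23 and Nlrc5, the latter an activator of class I genes, had log2 fold changes of 0.95 ± 0.21 and 2.25 ± 0.52 (SE). The marker medians given for the interferon list apply here as well.

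The homeostatic microglia list was lower as a group, with a median of -0.17 over 24 genes (camera adjusted p = 0.0015, adjusted p = 0.482 with an estimated correlation). Its median was -0.26 without the library labelled Pd1cKO-Cx3 replicate 2 and -0.12 without the library labelled Pd1cKO-Cx3 replicate 3. Cx3cr1 and Fcrls fell over all genes tested in edgeR. Fcrls starts at 87250758 on chromosome 3, where Tpm3 starts at 90072649, and whether a variant in this region affects both was not tested. The labels do not say whether Cx3 names a driver placed in Cx3cr1, nor whether the controls carried it. Without Cx3cr1, a setting added after seeing the data, the list median was -0.13 (camera adjusted p = 0.0052). Adjusted over the list alone 7 fell and 17 did not pass. P2ry12, a purinergic receptor gene of resting microglia, had 14998 ± 186 CPM in Pd1fl/fl and 11001 ± 439 CPM in the libraries labelled Pd1cKO-Cx3 (SD, n = 2), and passed over the list alone but not over all genes (edgeR adjusted p = 0.0959). P2ry13 and Adgrg1 had log2 fold changes of -0.46 ± 0.07 and -0.53 ± 0.11 (SE). The list of activated and axon-tract microglia was higher, with a median of 0.38 over 24 genes (camera adjusted p = 0.0008, adjusted p = 0.407 with an estimated correlation, and 0.0634 without Pd1fl/fl replicate 2). None of its members passed edgeR over all genes, while DESeq2 on 20308 genes called Axl. Adjusted over the list alone 2 rose, the receptor tyrosine kinase gene Axl (27.3 ± 9.25 against 136 ± 38.7 CPM) and the lysosomal protease gene Ctsb (4885 ± 75.2 against 5921 ± 166 CPM). Cd9 and Spp1 had log2 fold changes of 0.36 ± 0.10 and 0.94 ± 0.29 (SE). Gpnmb had 0 counts in both controls and 14 and 19 in the libraries labelled Pd1cKO-Cx3, at least 5.66-fold higher. The border-associated macrophage markers, which overlap with what activated macrophages express, had a median of 0.85.

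Cell cycle genes were higher as a group, with a median of 0.57 over 36 genes, 35 of them with a positive fold change (camera adjusted p = 2.7e-07, adjusted p = 0.493 with an estimated correlation). Without a library the median ranged from 0.36 (without the library labelled Pd1cKO-Cx3 replicate 3) to 0.85 (without Pd1fl/fl replicate 2). None passed over all genes or adjusted over the list alone. Birc5 had 67.5 ± 1.75 CPM in Pd1fl/fl and 107 ± 10.3 CPM in the libraries labelled Pd1cKO-Cx3 (SD, n = 2), and Ccna2 had 15.9 ± 0.125 and 33.7 ± 6.16 CPM. Top2a, Plk1 and Cdt1 had log2 fold changes of 0.55 ± 0.16, 0.99 ± 0.30 and 0.98 ± 0.32 (SE). The endothelial, mural and border-associated macrophage marker lists had medians of 0.91, 1.04 and 0.85. The list of dissociation and immediate-early genes was lower, with a median of -0.36 over 33 genes (camera adjusted p = 0.0021, adjusted p = 0.493 with an estimated correlation). None passed edgeR over all genes, while DESeq2 on 20308 genes called 7 lower. Adjusted over the list alone in edgeR 6 fell, among them Fosb (246 ± 23.8 against 103 ± 1.33 CPM), Junb, Zfp36, Egr1 and Fos, with log2 fold changes from -1.26 to -0.56. These are genes that tissue handling is known to induce. The groups overlapped in the mean log2 CPM of the whole list. Relative to the control mean it was -0.21 and 0.21 in Pd1fl/fl replicates 1 and 2. It was -0.35 and -0.19 in the libraries labelled Pd1cKO-Cx3 replicates 2 and 3. The camera call was lost without Pd1fl/fl replicate 2 (median -0.12, adjusted p = 0.275) and without the library labelled Pd1cKO-Cx3 replicate 2 (-0.38, adjusted p = 0.159), and the median was -0.64 without Pd1fl/fl replicate 1.

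Several marker lists of other cell types differed with the genotype labels. The border-associated macrophage list had a median of 0.85 over 17 genes (camera adjusted p = 0.0003, adjusted p = 0.407 with an estimated correlation). Without a library it ranged from 0.67 (without the library labelled Pd1cKO-Cx3 replicate 2) to 1.36 (without Pd1fl/fl replicate 1). None passed edgeR over all genes, while DESeq2 on 20308 genes called 4 higher. Adjusted over the list alone in edgeR 6 rose, among them F13a1, Cbr2, Lyve1, Siglec1 and Cd163. Lyve1 stood at 23.1 ± 6.93 CPM in Pd1fl/fl and 65.8 ± 10.6 CPM in the libraries labelled Pd1cKO-Cx3 (SD, n = 2). Siglec1 is itself induced by interferon. The endothelial list had a median of 0.91 over 19 genes (camera adjusted p = 0.0015, adjusted p = 0.407 with an estimated correlation, and 0.227 without the library labelled Pd1cKO-Cx3 replicate 2, where the median was 0.44). None of its members passed edgeR over all genes or adjusted over the list alone, while DESeq2 on 20308 genes called Tie1. Kdr had 12.8 ± 5.72 and 26.0 ± 0.809 CPM and Cldn5 20.4 ± 5.63 and 37.6 ± 13.8 CPM, while Tie1, Esam and Ly6a had log2 fold changes from 1.54 to 5.22. Tie1, the highest, had 0 and 6 counts in Pd1fl/fl and 162 and 64 in the libraries labelled Pd1cKO-Cx3 replicates 2 and 3. The mural and fibroblast list had a median of 1.04 over 14 genes (camera adjusted p = 0.0015, adjusted p = 0.407 with an estimated correlation). Without a library, where the filter kept more genes, it ranged from 1.19 (without the library labelled Pd1cKO-Cx3 replicate 2) to 2.31 (without Pd1fl/fl replicate 1). None passed edgeR over all genes, while DESeq2 on 20308 genes called 3 higher. Adjusted over the list alone in edgeR 4 rose, Igfbp2, Notch3, Rgs5 and Myl9. Rgs5, a pericyte gene, stood at 33.0 ± 18.7 and 95.3 ± 13.2 CPM. Notch3 and Anpep had 0 counts in both controls and were at least 23.4-fold and 3.97-fold higher. Notch3 had 19 and 121 counts in the libraries labelled Pd1cKO-Cx3 replicates 2 and 3, with a bound of 6.82-fold from replicate 2 alone. The matrix remodelling list, which holds genes of such cells, had a median of 0.31 over 26 genes (camera adjusted p = 0.0052, adjusted p = 0.407 with an estimated correlation, and 0.159 without the library labelled Pd1cKO-Cx3 replicate 2). The median was 0.51 to 0.54 in the 4 fits without a library and 0.51 at 5 CPM in 2 libraries. None of its members passed over all genes or adjusted over the list alone. Mmp2, Col1a1, Col4a2, Col1a2 and Fn1 had log2 fold changes from 0.88 to 1.59.

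The lymphocyte list had a median of 1.14 over 8 genes (camera adjusted p = 0.010, adjusted p = 0.407 with an estimated correlation). Adjusted over the list alone 2 rose, the B cell gene Ms4a1 and Cd4, both at 0 counts in the controls and at least 9.82-fold and 12.9-fold higher. Cd4 had 56 and 17 counts in the libraries labelled Pd1cKO-Cx3 replicates 2 and 3, bounds of 20.1-fold and 5.62-fold from each alone. Cd79a had 2 counts in the controls and 52 in the libraries labelled Pd1cKO-Cx3, a ratio of 26.9 (exact 95% binomial interval 7.08 to 228). Igkc and Ighm had log2 fold changes of 2.12 ± 1.81 and -0.10 ± 0.10 (SE). Of the 8 genes 5 had positive and 3 negative fold changes. The call was lost without Pd1fl/fl replicate 2 (median 0.66, adjusted p = 0.134) and without the library labelled Pd1cKO-Cx3 replicate 2 (0.14, adjusted p = 0.159), and the median was 3.61 without Pd1fl/fl replicate 1. The astrocyte, neuron, oligodendrocyte lineage, and monocyte and neutrophil lists did not pass, with medians of 0.17, 0.02, 0.46 and -0.38 (camera adjusted p = 0.328, 0.637, 0.302 and 0.310). The oligodendrocyte list passed without Pd1fl/fl replicate 1 (1.13, adjusted p = 0.0136) and, like the astrocyte list, without the library labelled Pd1cKO-Cx3 replicate 3 (0.88 and 0.59, adjusted p = 0.00265 and 0.000772), and the monocyte and neutrophil list passed without Pd1fl/fl replicate 2 (-1.17, adjusted p = 0.0467). The astrocyte genes Gfap, Mlc1 and Slc4a4 had log2 fold changes from 0.66 to 1.43, the neuronal genes Tubb3, Map2 and Stmn2 from 0.44 to 1.49, and the oligodendrocyte lineage genes Sox10, Pdgfra and Mog from 1.24 to 1.93, none past the threshold over its list alone. Mog had 7.35 and 1.48 CPM in Pd1fl/fl and 27.8 and 6.26 CPM in the libraries labelled Pd1cKO-Cx3, so the groups overlapped. Of the monocyte and neutrophil list, Retnlg had 28 counts in the controls and 5 in the libraries labelled Pd1cKO-Cx3, and Plac8 rose adjusted over the list alone (17.1 ± 0.322 against 69.2 ± 2.67 CPM). The ependymal, erythroid and sex-linked lists had 1, 4 and 4 tested genes and were not tested. Enkur, Alas2 and Kdm5d, from these 3, did not pass over all genes (edgeR adjusted p = 0.831, 0.894 and 0.900).

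**Figure D3:**
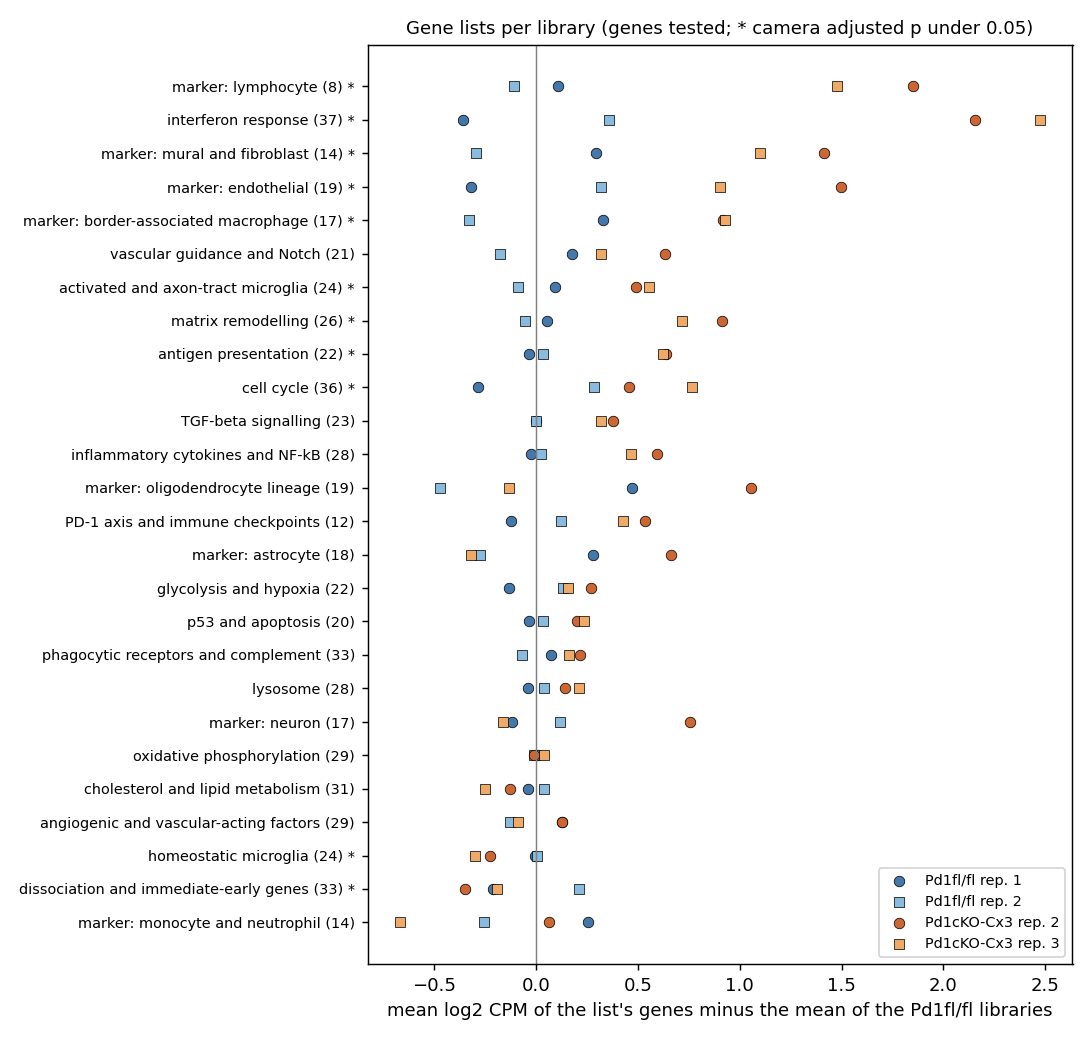
Mean log2 CPM of each gene list in each of the 4 libraries, relative to the mean of the Pd1fl/fl libraries, with the number of genes tested in brackets and an asterisk where camera passed. The interferon response list, with 37 genes, lies highest among the lists that are not markers of other cells, and the endothelial, mural and border-associated macrophage markers lie on the same side.

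Lists of functions close to the study's subject did not pass. Angiogenic and vascular-acting factors had a median log2 fold change of -0.18 over 29 genes (camera adjusted p = 0.637). Thbs1 had 6.38 ± 1.02 CPM in Pd1fl/fl and 14.4 ± 3.20 CPM in the libraries labelled Pd1cKO-Cx3 (SD, n = 2). Hbegf had 17.9 ± 3.82 and 9.97 ± 2.86 CPM in the same order. The vascular guidance and Notch list had a median of 0.13 over 21 genes (camera adjusted p = 0.229), with Ephb4 at 0 counts in both controls and at least 14.8-fold higher. Hes1 had 4 and 1 counts in Pd1fl/fl and 19 and 71 in the libraries labelled Pd1cKO-Cx3 replicates 2 and 3. Notch4 and Hes1 had log2 fold changes of 3.34 ± 0.88 and 4.13 ± 1.35 (SE). These genes are also expressed by vessels, and the endothelial and mural marker lists had medians of 0.91 and 1.04. Phagocytic receptors and complement had a median of 0.03 over 33 genes (camera adjusted p = 0.746), with Fcgr1, Rac2 and Itgb2 between 0.23 and 0.39. TGF-beta signalling had a median of 0.04 over 23 genes (camera adjusted p = 0.383), with Pmepa1 at -0.48 ± 0.14 and Id1 at 1.24 ± 0.42 (SE). Tgfb3, of the same list, had 0 counts in both controls and was at least 8.12-fold higher in the libraries labelled Pd1cKO-Cx3. The bound was 4.67-fold from the 13 counts of the library labelled Pd1cKO-Cx3 replicate 2 alone. In no list of this paragraph did a member pass edgeR over all genes or adjusted over the list alone. DESeq2 on 20308 genes called 1, Ephb4.

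The remaining lists did not pass either. The PD-1 axis and immune checkpoint list had a median of 0.05 over 12 genes (camera adjusted p = 0.389), and adjusted over the list alone Lgals9 and Ptpn11 rose and Vsir fell. The lysosome list had a median of 0.11 over 28 genes (camera adjusted p = 0.0898, but 0.0413 at 5 CPM in 2 libraries and 1.8e-06 on DESeq2 statistics), and adjusted over the list alone 8 rose. Psap, the precursor of lysosomal activator proteins, stood at 6460 ± 146 and 8952 ± 184 CPM, Grn at 3000 ± 87.7 and 4027 ± 43.5 CPM, and Ctss at 2224 ± 86.8 and 3244 ± 346 CPM (SD, n = 2). In the inflammatory cytokine and NF-kB list (median 0.12 over 28 genes, camera adjusted p = 0.0898), the chemokine gene Ccl5 rose adjusted over the list alone, with 0.581 ± 0.156 against 10.4 ± 3.53 CPM, and Ccl12 and Birc3 had log2 fold changes of 0.62 ± 0.19 and 0.60 ± 0.24 (SE). The p53 and apoptosis list had a median of 0.18 over 20 genes (camera adjusted p = 0.199, but 0.0257 at 5 CPM in 2 libraries), with Ccng1, Cdkn1a and Sesn2 between 0.50 and 0.74. Glycolysis and hypoxia had 0.11 over 22 genes (adjusted p = 0.199), oxidative phosphorylation 0.04 over 29 genes (0.875), and cholesterol and lipid metabolism -0.08 over 31 genes (0.279), all by camera and with no member past the threshold over the list alone. In these 3 lists, Pgk1, Ldha and Bnip3 had log2 fold changes from -0.55 to 0.49, Atp5b, Atp5a1 and Ndufb3 from -0.43 to 0.44, and Abca1 and Scd2 of -0.29 and -0.41.

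Among 1071 biological process terms, 5 were higher and 0 were lower. The term for the response to virus held 76 genes with a median log2 fold change of 0.39 (camera adjusted p = 0.000222), and that for the cellular response to interferon-beta 34 genes with 0.53 (adjusted p = 0.0017). A pair of class I antigen presentation terms, of 21 and 36 genes, had medians of 0.62 and 0.31 (adjusted p = 0.0104 and 0.0158). The term for positive regulation of T cell mediated cytotoxicity held 20 genes with 0.54 (camera adjusted p = 0.0158). Most of its genes also stood in another of these terms, so it is not a separate result. With an estimated correlation 0 terms passed (camera adjusted p = 0.990 for each of these 5). That setting rests on 2 residual degrees of freedom over 1071 terms, so it could hardly pass any. The border-associated macrophage, endothelial, mural and lymphocyte marker lists had medians of 0.85, 0.91, 1.04 and 1.14. Without Pd1fl/fl replicate 1, 0 terms passed, and 1 passed without the library labelled Pd1cKO-Cx3 replicate 2 or replicate 3.

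In the authors' deposited tables, each of which compares 2 libraries and not the genotypes, 5139 to 5984 genes were called, 27.6% to 33.2% of those listed. All 4 of the authors' deposited tables called 654 genes higher and 254 lower in the library labelled Pd1cKO-Cx3, and 27 of the 37 interferon genes were among those higher. The tables share libraries. In 20 simulations with no difference between the groups, a rebuilt version of the authors' rule called 325 genes higher and 329 lower in all 4 tables, against 13.2 and 3.36 for independent lists. The rebuilt rule gave the same call as the authors' deposited tables in 98.3% of cases and called 583 genes higher and 223 lower. It called 806 genes in both directions together, against 579 and 610 when the 4 libraries were paired across genotypes. With no difference between the groups, the simulations gave 653.8 genes in both directions together. The 223 lower calls did not exceed the 329 simulated, while the 583 higher calls exceeded the 325. Much of the overlap may thus come from the shared libraries.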

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

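The missing-count, protein-coding and filtered DESeq2 settings and the list without Cx3cr1 were chosen after seeing the data, and all other settings were planned. No paired analysis was possible because the groups share only 1 replicate number. The count of 6 changed genes became 32 with every gene above 0 counts, 32 at 5 CPM in 2 libraries, 220 with DESeq2 on all 20308 genes, 234 with DESeq2 on the 15097 that edgeR tested (208 called in both), 29 with limma-voom, 1 at adjusted p under 0.01 and 19 under 0.1. It ranged from 4 to 21 without a library, highest without Pd1fl/fl replicate 2. With the 2 filters and limma-voom the higher share moved from 3 of 6 to 68.8%, 68.8% and 65.5%, and with DESeq2 to 76.8% and 76.5%, and without a library it ranged from 25% (without Pd1cKO-Cx3 replicate 3) to 76.2% (without Pd1fl/fl replicate 2). With upper-quartile factors it was 40%. The cause was not tested. Protein-coding genes alone gave 8. Missing counts taken as 4 moved nothing, since 0 tested genes had one. Pdcd1 stayed higher and unpassed in every setting, at 5.30 with limma-voom, 4.15 with limma-trend and 1.94 to 10.42 without a library. The 11 lists that passed became 0 with an estimated correlation, 3 with fry (matrix remodelling, antigen presentation and lymphocyte), and 8 to 13 without a library. fry asks whether a list's genes move one way and does not compare them with other genes. With an estimated correlation, camera had 2 residual degrees of freedom, so its loss of all calls does not measure correlation alone. The 5 terms became 0 with an estimated correlation and 0 to 4 without a library. The authors' 908 calls common to all tables became 545 at an absolute log2 fold change over 2 and 541 with their adjusted p under 0.001.

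Direction turned for values that did not pass in the main fit. Over the 4 fits without a library, the log2 fold change ranged from -0.163 to 1.59 for Hba-a1, -0.0803 to 1.43 for Hbb-bs, -0.568 to 13.6 for Eif2s3y (the latter without Pd1fl/fl replicate 2, where it passed at adjusted p = 0.0103 against a lone control at 0 counts, so that the prior count sets the value), -0.0611 to 0.00287 for Tmem119 and -0.0557 to 0.145 for Aif1, and the list median from -0.145 to 0.0803 for angiogenic factors, 0.0157 to 0.0486 for oxidative phosphorylation, -0.398 to 0.586 for astrocytes, -0.183 to 0.485 for neurons and -0.438 to 1.13 for oligodendrocytes. At 5 CPM the phagocytic (-0.0388), TGF-beta (-0.0534), oxidative phosphorylation (0.01) and monocyte and neutrophil (-0.261) lists turned. Oxidative phosphorylation (0.0457) turned with every gene above 0 counts, and the monocyte list (-0.272) with DESeq2 statistics. For lists the direction is camera's, which can differ in sign from the median. Apart from Y-linked Eif2s3y, the cause was not tested. Without a library, the medians of lists that did not pass in the main fit ranged from 0.0208 to 0.130 for the PD-1 axis, -0.0133 to 0.0532 for phagocytic receptors, 0.0552 to 0.227 for lysosome, 0.0123 to 0.332 for vascular guidance, 0.00715 to 0.170 for TGF-beta, 0.0834 to 0.299 for cytokines, 0.0321 to 0.246 for glycolysis, -0.130 to -0.0124 for cholesterol, 0.140 to 0.310 for p53 and -1.17 to -0.193 for monocytes and neutrophils. Of the other values for single genes, 1304 kept their side, 85 newly passed and 7 no longer passed, and of those for lists 239, 7 and 26.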

Other observations

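The tests of sex, of unchanged other cells, of exchanged labels, of summed tropomyosin counts and of the other splits were chosen only after the result was seen. Genes outside the lists also differed by DESeq2, and those named in this paragraph were chosen after their values were seen. Among its calls, the interferon-related genes Phf11b, Phf11d, Slfn5 and Lgals3bp had log2 fold changes of 2.66, 1.96, 1.78 and 1.56, and Ly6e had 0.71. The actin-binding gene Cotl1 had 1.33 ± 0.16 (SE) and the stem and endothelial cell gene Cd34 1.73 ± 0.28. Fcrl1, an Fc receptor-like gene of B cells, had -2.80 ± 0.48. The mitochondrial genes mt-Co1, mt-Rnr2 and mt-Nd4 had 0.54, 0.53 and 0.44. These calls come from the run on 20308 genes, and the false share of 34.1% seen in simulated data comes from 15097. Genes at 0 counts in 1 library with at least 2 CPM in each other numbered 50 and 33 in Pd1fl/fl replicates 1 and 2, and 1 and 16 in the libraries labelled Pd1cKO-Cx3 replicates 2 and 3.

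The interferon response list was higher in the libraries labelled Pd1cKO-Cx3, and sex of the libraries as the whole cause is argued against by the median of 1.81 without the control library that holds Xist. More cells of other types in an unchanged state would raise transcripts by no more than their markers, and the lower quartile of the list (1.49) lay above the highest median of 8 marker lists (1.14), but that median comes from 8 lymphocyte genes, 3 of them with negative fold changes, and it reached 3.61 without Pd1fl/fl replicate 1, so this bound decides nothing. A regression on border macrophage and endothelial markers gave 3.21 where a value over 1 had been set beforehand as evidence against such cells, but the marker score itself separates the groups and leaves 1 residual degree of freedom, so that bound was wrong for this design and the contribution of such cells, perhaps themselves in an interferon-induced state, cannot be told apart from the genotype. PD-1 loss, the driver and unlabelled litter differences stay open and untested.

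Pdcd1 was higher where the label names its deletion. Of 5415 genes with 2 to 20 CPM, 0.157% were as far apart without overlap in the other 2 splits of the libraries, which argues against the scatter usual at low counts, and 0.425% were in the real split. Pdcd1 is, however, 1 of the 50 genes at 0 counts in Pd1fl/fl replicate 1 with at least 2 CPM in each other library and the edgeR test did not pass, so a loss of its reads in that library stays open, as untested. Exchanged genotype labels would be a candidate explanation. If "Cx3" stands for a driver placed in Cx3cr1, however, the log2 fold change of -1.29 at Cx3cr1 would go with the labels as given. The labels do not spell this out, so exchanged labels stay open. A retained, untranslated transcript could leave reads after a deletion, but by itself does not account for a level above both controls. The marker medians of other cell types given for the interferon list apply here as well. Reads within the gene were not analysed here.

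Tpm3-rs7 was higher and Tpm3 lower in the libraries labelled Pd1cKO-Cx3. The log2 fold change of their summed CPM was -0.23, which is consistent with reads moving between the 2 copies. Among 56 processed pseudogenes with at least 10 CPM, 1 (1.79%) lay over 2 log2 units apart without overlap. The share was 0.47% (39 of 8297) among protein-coding genes. This argues against so large a counting difference for all processed pseudogenes, and smaller ones are not covered. Tpm3-rs7 is itself annotated as protein-coding, so the 56 do not include it. The processed pseudogenes Rps3a3 (-3.39 ± 0.28) and Rps3a2 (1.23 ± 0.17), chosen after their values were seen, moved in opposite directions while Rps3a1 had 0.25 ± 0.14 (SE). A strain variant at the parent gene that changes where reads align best stays open and was not tested. Rps3a1 starts at 86137940 on chromosome 3, in the same region as Fcrls (87250758) and Tpm3 (90072649). These cases may therefore not be separate, and whether a variant in this region affects them together was not tested.

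The 4 libraries make 3 splits into pairs, too few for a share under 0.05. The real split, the 1 split with as many changed genes, gave 6, and the highest other gave 0, with 461 and 476 genes at an unadjusted p under 0.05 in edgeR. By camera with the preset correlation the real split passed 11 lists and the others 4 and 0, with a p for the interferon list of 9.1e-27 in the real split and 0.0470 and 0.920 in the others.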
